A study of Aedes albopictus with 6 samples.

How the data were processed

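Small RNAs were sequenced from whole bodies of the Asian tiger mosquito, Aedes albopictus, with 3 libraries titled Female and 3 titled Male. Per the labels' protocols, total RNA was isolated with TRIzol, small RNAs were taken from a denaturing polyacrylamide gel, and adaptors were ligated to both of their ends. The read trimmer Trimmomatic 0.30 was used, per the submitters' processing notes. The aligner, the counting program, the genome build, the filter that chose the tags and the way the 3 libraries of a sex were combined are not given in the sources used here.

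The deposited table held 1 line per small RNA tag, with its position, 1 count column per sex, 1 TPM column per sex and 1 log2 column. The deposited counts were whole numbers per tag that had not been normalised. The smallest count above 0 was 2 in both columns, no value of 1 occurred, and a listed 0 can therefore stand for 0 or for 1. The authors deposited TPM values, a unit named per the file headers. Checked against the counts, each equalled the count divided by a total that was the same for every tag of a column and scaled to a common sum, with a count of 0 written as 0.01 and with no length term. The log2 values that the authors deposited equalled the log2 of the male over the female TPM value, so a positive value is higher in males. The smallest absolute value in that column was 1.00, so the list held only tags at least 2-fold apart, and the smallest sum of both counts was 6. Because the list was chosen on these same samples, the direction of its members is not independent evidence.

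The total behind each TPM column was recovered from the constant ratio of TPM to count, and was 2677063 for females and 2060047 for males. Levels are given as TPM, the count scaled by these totals. The design, the rule for tags to name and part of the alternatives were fixed before the data were examined. The design assumed replicated counts and edgeR's quasi-likelihood test. With 1 column per sex there were no residual degrees of freedom, so no test across tags was run, no p-value is given, and a difference is a difference between the 2 columns. The 3 libraries per sex were not analysed singly here. Each count has an exact 95% Poisson interval, and each ratio of counts an exact conditional (Clopper-Pearson) 95% interval scaled by the totals. Shares have exact Clopper-Pearson 95% intervals. For shares of tags these take tags as independent, though many overlap, so they are likely too narrow. Reads without molecular identifiers are not independent molecules, so intervals of counts, ratios of counts and shares of counts cover counting error only. No interval covers the spread between mosquitoes or libraries. No fold is given against a listed 0.

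The rule for tags to name took the 6 most abundant tags per direction, the 6 with the largest fold per direction among those with a mean TPM of at least 10, the 3 highest in each sex, and the piRNA of the series title, Aalpi18529. No replicate condition could be applied. The level of Aalpi18529 was not analysed here. The tags with the largest fold all came from those listed at 0 in the other sex, and they were ranked by the deposited log2 value. The deposited table does not pair its tags with gene or piRNA names, so tags are identified by position, and the table's own ID is printed for 2 tags per direction. Regions were described after their values were seen. Most were taken from the 12 nuclear regions with most tags, and the 4 with most counts of the leading sex among those with 90% or more, or 10% or fewer, male-higher tags.

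Positions are given as in the table, on scaffold sequences (names beginning NW) and on NC_006817.1, the mitochondrial sequence of the species. Neither strand nor tag sequence was used here, and no gene, exon or repeat annotation of that build was used here. The planned analyses of base composition, sequence families and miRNA lists were therefore not run. Tags with gaps of at most 10 kb on one sequence formed a region if there were 5 or more. Tags that overlapped were also merged to loci. The share of male-higher tags on the mitochondrial sequence and in each picked region was set beside 10000 random lists of the same size matched on mean abundance in 10 bins, and the directions of neighbouring loci beside 10000 shuffles. The random lists drew tags singly and did not keep overlapping tags together, so their ranges are likely too narrow. Partners of the ping-pong type were counted from positions, as the last base of a tag reaching 10 bases into another, against the mean number for 8, 9, 11 and 12 bases.

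Scaling alternatives were the totals of the listed tags and the TMM, RLE and upper quartile factors of edgeR 4.0.16 in R 4.3.3. They were computed on a list that lacks unchanged tags. Other alternatives were a minimum TPM of 10, tags of 24 to 30 nt, omission of the 10 most abundant tags, other count minimums, thinning of the female counts to the male total (100 draws), other region settings, and merged loci. Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. The interval was tested on simulated data at the mean rates of 22759 tags for the male over female comparison, 200 of them changed. It held the true ratio for 97.9% of tags and excluded 1 for 2.11% of the 22559 unchanged tags. It lay above 1 for 20%, 36%, 46% and 76% of 50 tags each raised 2-, 4-, 8- and 16-fold.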

Results

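Small RNAs from whole bodies of 2-day-old Aedes albopictus adults, virgin females and males, were compared to describe how PIWI-interacting RNAs (piRNAs), a class of small RNAs that silence transposons in animal germ lines, differ between the sexes. The labels give 3 libraries per sex, and the deposited table gives 1 count per tag and sex, so each value is a single value per sex with no replicate check. The totals implied by the table were 2677063 counts in females and 2060047 in males. The table listed 22773 tags of 24 to 33 nt on 686 sequences, all at least 2-fold apart between the sexes. These tags held 268842 female counts, 10% of the female total, and 222446 male counts, 10.8% of the male total. TPM is the count scaled to the total of its column, with no length term. Brackets give 95% intervals, which for counts, ratios of counts and shares of counts cover counting error only. Those of shares of tags take tags as independent. As overlapping tags merged the 22773 tags to 17539 loci, these are likely too narrow.

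Tags under 2-fold are not in the list and may have higher counts. Among listed tags, those with the most counts in males came from few positions. The highest, t00000734 at NW_021839020.1 25193107 to 25193130 (24 nt), had a TPM of 2565 in males and 515 in females, a ratio of 4.98 (4.69 to 5.29). A 27-nt tag ending on the same base, at 25193104 to 25193130, was 6.08-fold (5.56 to 6.67) higher in males. On NW_021837045.1, tags of 26 and 27 nt that both started at base 35726 were 3.62-fold (3.40 to 3.86) and 6.90-fold (6.24 to 7.65) higher in males. The 25-nt tag at NW_021837156.1 57217612 to 57217636 was 2.65-fold (2.51 to 2.79) higher in males and had a TPM of 2043 there. The 28-nt tag at NW_021839130.1 38474546 to 38474573 was the highest of the listed tags in females, at a TPM of 1028. It nevertheless stood at 2160 in males, a ratio of 2.10 (2.00 to 2.20). Its ratio turned to 0.93 when RLE factors replaced the implied totals.

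Among tags higher in females, t00001939 at NW_021837226.1 47873 to 47898 (26 nt) stood apart from the other abundant ones. It had a TPM of 864 in females and 35.9 in males, 24.1-fold (19.1 to 30.8) higher in females. The other 5 of the 6 most abundant female-higher tags were between 2.01-fold and 2.42-fold higher. The most abundant of them, the 27-nt tag at NW_021838798.1 80025477 to 80025503, had a TPM of 943 in females and 389 in males, 2.42-fold (2.24 to 2.63) higher. The 26-nt tag at NW_021839130.1 50173541 to 50173566 was 2.01-fold (1.79 to 2.27) higher, so its interval reached below the 2-fold edge of the list. Tags of 31 nt at NW_021838153.1 168066301 and of 33 nt at NW_021837045.1 125969329 were 2.20-fold (1.97 to 2.48) and 2.40-fold (2.09 to 2.76) higher in females.

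**Figure D1:**
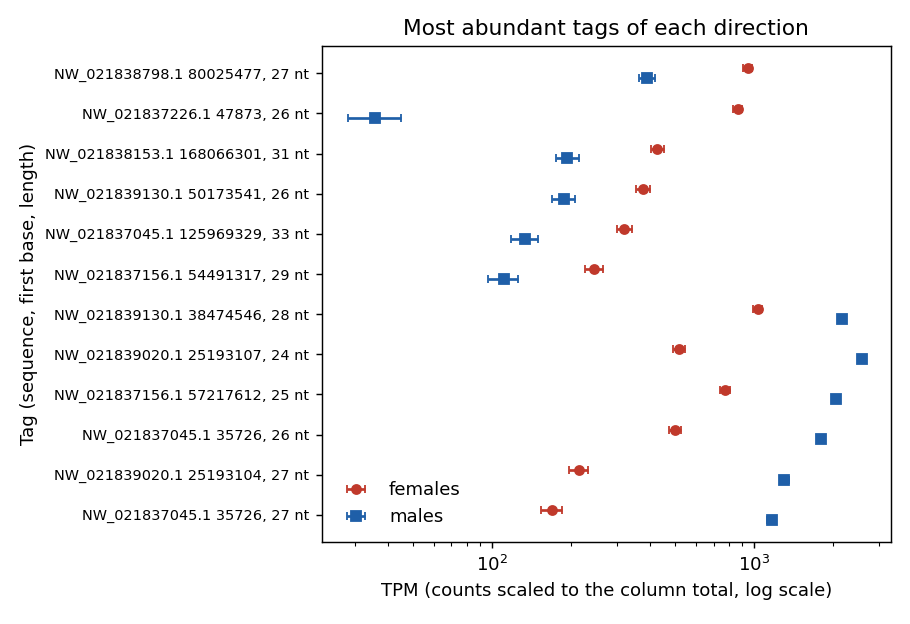
TPM (log scale) in females (circles) and males (squares) for the 6 most abundant tags of each direction, labelled by scaffold, first base and length, with bars for exact 95% Poisson intervals. The tag starting at NW_021837226.1 47873 has the widest gap, 864 in females against 35.9 in males.

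Other tags had counts in one sex and were listed at 0 in the other. The highest in females was t00012116 at NW_021838687.1 12619927 to 12619954 (28 nt), with 343 counts (308 to 381) and 0 listed in males. It was followed by tags starting at NW_021838153.1 96895850 with 123 counts, NW_021837045.1 43568115 with 114 and NW_021837600.1 41743028 with 100. The highest in males was t00026247 at NW_021837045.1 190118575 to 190118604 (30 nt), with 140 counts (118 to 165) and 0 listed in females. The tags starting at NW_021838222.1 753207 and NW_021838721.1 1633689 had 117 and 114 counts in males. A pair of tags of 29 and 30 nt starting at NW_021837156.1 57227850 had 112 and 94 counts in males and lay in the same region as the abundant male-higher tag at 57217612. In all, 12682 tags were listed in females alone, 334 of them with 20 or more counts, and 3868 in males alone, 112 of them with 20 or more. The median count was 7 in both sets. With the female counts thinned to the smaller male total and at least 6 counts required, a median of 6894.5 tags over 100 draws were listed in females alone and 4201 in males alone. Tags with 2 female counts were listed only from 9 male counts on. Tags with fewer male counts, whose female count thinning could turn to 0, are absent, so the male number is likely too low.

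By number of tags the list leaned to females. Of the 22773 tags, 15547 (68.3%, 67.7 to 68.9) were higher in females and 7226 were higher in males. The lean turned at higher levels, since among tags with a TPM of at least 10 in either sex 1090 were higher in females and 1861 in males. Among the 6223 tags counted in both sexes, the median fold was 3.85 for the 2865 female-higher tags and 4.26 for the 3358 male-higher tags. This order rested on the scaling, since the medians were 4.14 and 3.97 with the totals of the listed tags and 5.13 and 3.19 with TMM factors. At least 8-fold apart were 170 female-higher and 466 male-higher tags of that set, but 439 and 221 with TMM factors. The counting interval of the ratio excluded 1 for 10167 female-higher and for all 7226 male-higher tags. These numbers depended on the settings, and the majority turned to males, with 4971 female-higher and 5827 male-higher tags, if a listed 0 was taken as 1 count. With RLE factors they were 15551 and 1924. The filter behind the list is not given in the sources used here, and a filter that tested the counts would itself set these numbers. The edge of the list was not even, since at 10 counts in the lower sex the smallest listed difference in TPM was 2.60-fold for male-higher tags (20 counts) and 2.00-fold for female-higher tags (26 counts). A higher edge by itself tends to raise the median fold of male-higher tags, so the order of the 2 medians above may also come from the list. Within the list, counts were more concentrated in males, where the 10 most counted listed tags held 12.7% of the listed counts, against 6.01% in females. Of the implied totals they held 1.37% and 0.60%. As tags under 2-fold are not listed, concentration over all tags of a sex is not known.

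Other scalings moved every male over female ratio by the same amount. The shift on the log2 scale was -0.10 with the totals of the listed tags, -0.42 with TMM, -0.44 with upper quartile and -1.17 with RLE factors. As every tag was listed at least 2-fold apart, only the RLE shift could turn any tag, and it turned 246 male-higher tags.

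The listed tags of the mitochondrial sequence, NC_006817.1, were almost all male-higher. There were 469 listed tags between bases 262 and 12506, of which 466 were higher in males, and the 3 higher in females had 6 or 7 female counts each. The summed TPM of the 469 tags was 8073 in males and 1045 in females, a ratio of 7.73 (7.42 to 8.05). They made up 7.48% (7.37 to 7.59) of the listed male counts and 1.04% (1.0 to 1.08) of the listed female counts. In 10000 random lists of 469 tags of matched abundance, the male-higher share ranged from 40.9% to 58.6%. These lists drew tags singly, while many mitochondrial tags overlap, so that range is likely too narrow. For tags of the lowest abundance bin, which held only tags listed in females alone, the drawn direction was fixed in advance. The ratio fell to 3.42 with RLE factors. Here and in the regions below, sums and ratios cover listed tags, each at least 2-fold apart, so they do not measure the whole of a sequence or region.

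On the nuclear scaffolds, tags lay in regions that often leaned to one sex. Tags at most 10 kb apart formed 486 regions of 5 or more tags, the mitochondrial one included, which held 69.6% (68.5 to 70.6) of the male-higher and 43% (42.2 to 43.7) of the female-higher tags. Overlapping tags counted singly, so a region could be 1 stack, as with 7 tags within 30 bases at NW_021838153.1 58187959. Merging overlaps left 4311 loci higher in males, from 7226 tags, and 12701 higher in females, from 15547. The shares of tags in regions thus mix such stacking with clustering, and merged loci were not used for them. In 134 of the 485 nuclear regions at most 10% of the tags were male-higher, and in 27 at least 90% were. The other 324 were mixed. Neighbouring nuclear loci had one direction in 67.9% of 8879 pairs, against a mean of 61.2% in shuffles, which ranged from 59.4% to 63.1%. Of the 12 nuclear regions with most tags, the male-higher share lay above the range of 10000 random lists of matched abundance in 5, below it in 2 and inside it in 5. The lists drew tags singly, so ranges that keep overlapping tags together would likely be wider. The lowest abundance bin held only tags listed in females alone, so the direction drawn from it was fixed in advance. The ranges, and the percentiles given below, partly reflect this. Some shares lay just past the range, with 46.6% above a highest of 45.4%, 49.8% above 48.6%, and 23.1% below a lowest of 24.7%.

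The 4 male-dominated regions with most male counts each spanned at most 7.75 kb. The region at NW_021837267.1 27236171 to 27243916 held 268 tags, 265 of them male-higher, and their sum was 8.0-fold (7.60 to 8.44) higher in males. At NW_021838798.1 2994086 to 3000357, 166 of 167 tags were male-higher, and their sum was 10.2-fold (9.31 to 11.3) higher. All 24 tags between bases 25193088 and 25193133 of NW_021839020.1, which include the listed tag with most male counts, were male-higher and together 5.38-fold (5.15 to 5.63) higher. On the same scaffold, 46 of 47 tags at 67138175 to 67141605 were male-higher, by 4.62-fold (4.32 to 4.94) in sum. A wider region at NW_021838965.1 577801 to 599721 (21.9 kb) held 31 tags, all male-higher, and their sum was 9.45-fold (7.34 to 12.3) higher in males. Other regions leaned to males less completely. At NW_021839130.1 50783825 to 50851441, 289 of 395 tags were male-higher and the sum was 2.90-fold (2.80 to 3.0) higher in males. At NW_021838602.1 269047 to 290783, 153 of 209 tags were male-higher and the sum was 2.89-fold (2.73 to 3.07) higher.

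Female-dominated regions included the source of the most female-biased abundant tag. At NW_021837226.1 36935 to 47913, 54 of 55 tags were female-higher, and the sum of 6001 female against 182 male counts was 25.4-fold (21.9 to 29.6) higher in females. Neighbouring regions on NW_021837600.1 were also female-dominated. The one at 41685871 to 41725499 had 140 of 152 tags female-higher and a sum 3.42-fold (3.17 to 3.70) higher, and the one at 41735615 to 41743779 had 132 of 134 and a sum 4.51-fold (4.14 to 4.93) higher. At NW_021838798.1 80015686 to 80025507, 9 of 10 tags were female-higher and the sum was 2.43-fold (2.25 to 2.63) higher. Unlike the 3 female-dominated regions above, its male-higher share, at percentile 3.06, lay inside the range of the matched random lists. The larger region at NW_021839130.1 50168091 to 50276698, on the scaffold that also carried a male-leaning region, had 329 of 369 tags female-higher and a sum 2.31-fold (2.21 to 2.41) higher in females. The region with the most nuclear tags, NW_021838599.1 5379067 to 5502690, had 333 of 433 tags female-higher and a sum 1.96-fold (1.87 to 2.06) higher. The other scalings all shifted ratios towards females, and the sums of the male-leaning regions named here stayed higher in males under all 4.

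Other tag-rich regions held tags of both directions. At NW_021837489.1 2319772 to 2363743, 198 of 425 tags were male-higher, and the sum was 1.22-fold (1.17 to 1.27) higher in males with the implied totals but lower in males with TMM, RLE and upper quartile factors. At NW_021837998.1 371515 to 474486, 131 of 349 tags were male-higher, and the ratio of sums was 0.99 (0.94 to 1.04) with the implied totals, 0.74 with TMM and 0.44 with RLE factors. Its male-higher share was at percentile 90.3 of the matched random lists. At NW_021837156.1 57184704 to 57269974, 97 of 283 tags were male-higher, at percentile 21.6. Its sum, which includes the abundant tag at 57217612, was nevertheless 1.48-fold (1.44 to 1.53) higher in males, and turned to 0.66 with RLE factors. These named regions were chosen after their values were seen, and whether their tags also match other positions is not given in the sources used here.

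**Figure D2:**
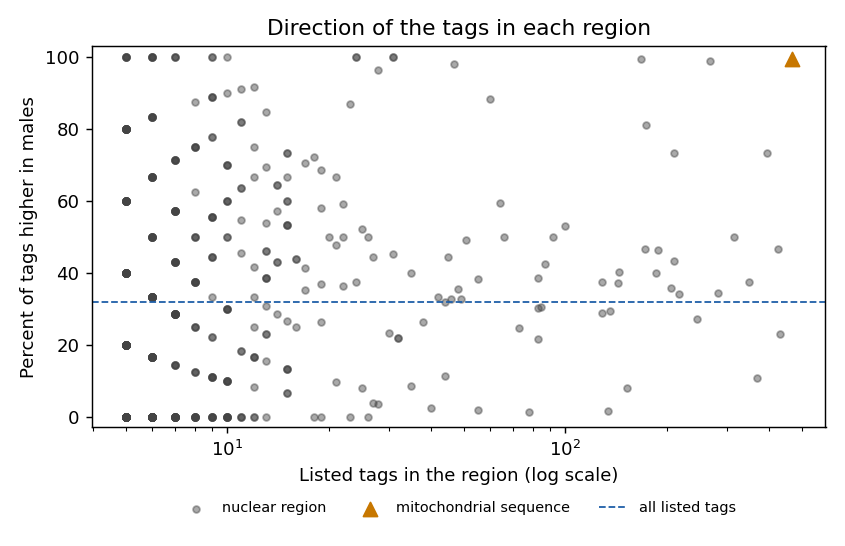
Percent of tags higher in males (vertical axis) against the number of listed tags (log scale) in each region, with circles for nuclear regions, a triangle for the mitochondrial sequence and a dashed line for all listed tags at 31.7%. The mitochondrial sequence, with 469 tags, and a nuclear region with 268 tags stand near the top.

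The listed tags were of piRNA size, and male-higher tags were spread more widely in length than female-higher ones. Tags of 24 to 30 nt held 97.0% of the listed female counts and 96.3% of the listed male counts. Tags of 24 or 25 nt made up 23.7% (22.7 to 24.7) of male-higher tags and 15.9% (15.3 to 16.4) of female-higher tags. Tags of 27 or 28 nt made up 39.1% (38.0 to 40.2) of male-higher and 51.7% (50.9 to 52.5) of female-higher tags. Tags of 31 to 33 nt made up 3.99% (3.55 to 4.46) of male-higher and 1.85% (1.64 to 2.07) of female-higher tags. Among mitochondrial tags, 38.2% (33.7 to 42.7) were 24 or 25 nt. In the 27 male-dominated nuclear regions the pooled share at 24 or 25 nt was 35.5% (32.1 to 39.1), and in the 134 female-dominated ones it was 11.1% (9.60 to 12.8). Tags of 31 to 33 nt made up 11.1% (8.95 to 13.6) and 2.98% (2.18 to 3.97) of these sets. Of the 757 tags in the male-dominated regions, 268 came from NW_021837267.1 27236171 and 167 from NW_021838798.1 2994086. There 37.3% and 47.9% were 24 or 25 nt, while smaller regions such as NW_021838532.1 997681 and NW_021838754.1 2150740 had none of that length.

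**Figure D3:**
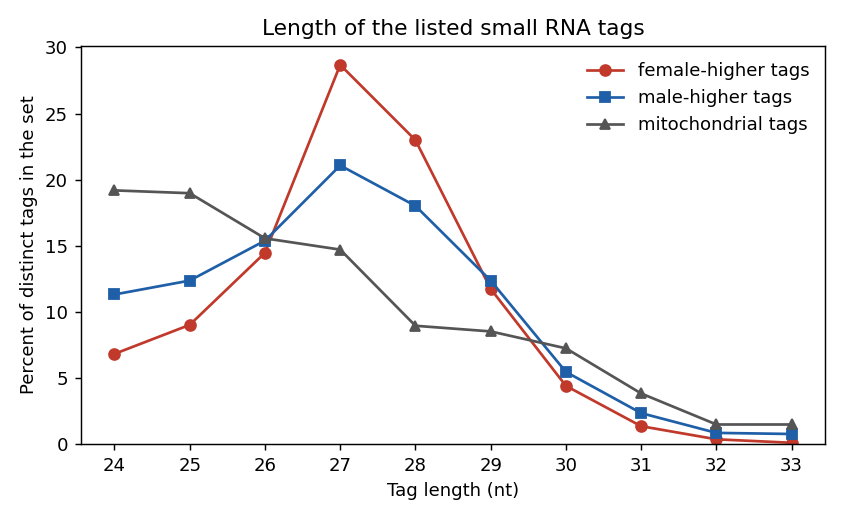
Percent of distinct tags (vertical axis) at each length in nt for female-higher tags (circles), male-higher tags (squares) and mitochondrial tags (triangles). Female-higher and male-higher tags peak at 27 nt, and mitochondrial tags peak at 24 nt.

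Overlaps of 10 bases between the ends of nuclear tags were somewhat more numerous than the mean of neighbouring distances when all tags were counted. The ping-pong cycle, in which piRNAs cut transcripts to make new piRNAs, leaves partners whose 5′ ends overlap by 10 bases. There were 259 pairs with a 10-base overlap, against 162, 185, 235 and 222 pairs at 8, 9, 11 and 12 bases, a ratio to their mean of 1.29 (1.12 to 1.48). Tags stacked on the same ends count in several pairs, and with each start and each end counted once the ratio was 1.18 (0.98 to 1.42), within counting error of 1. With stacked tags counted in full, the ratio was 1.34 (1.03 to 1.73) among female-higher tags and 1.33 (1.06 to 1.65) among male-higher tags. Male-higher tags had 109 pairs at 10 bases, but 108 at 11 and 98 at 12. Their ratio thus rested on the lower numbers of 52 and 71 at 8 and 9 bases. Female-higher tags had 81 pairs at 10 bases, against 59, 53, 65 and 65 at 8, 9, 11 and 12. In the male-dominated nuclear regions the ratio was 1.18 (0.86 to 1.61), and in the female-dominated ones it was 1.17 (0.73 to 1.82). Among male-higher tags outside the mitochondrial sequence and those male-dominated regions it was 1.51 (1.08 to 2.08). That set too had 54 pairs at 10 bases, but 48 at 11 and 47 at 12, with 17 and 31 at 8 and 9. For these subsets, ends were not counted once each. Mitochondrial tags had 48 pairs against a mean of 50, a ratio of 0.96 (0.69 to 1.32). Strand was not used here, so pairs on one strand could not be separated from pairs on opposite strands, and the number at 11 bases was close to that at 10.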

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

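Fixed before the data were examined were, for the split of tags between the sexes, the TMM, RLE and upper quartile scalings and the minimum TPM of 10, and otherwise the length limit, the omission of abundant tags, distinct tags in place of counts, and the count minimums and thinning at 3 counts; all others, including these scalings for other results, were chosen after the results were seen. Of 87 values under alternatives, 38 stayed within their interval or within 1.5 times the reported count, 41 moved, 1 lost its distance from 1 and 7 reversed. Outside these, the tag at NW_021839130.1 38474546 turned to a ratio of 0.93 with RLE, and the region at NW_021837489.1 2319772 to 0.91 with TMM, 0.54 with RLE and 0.90 with upper quartile. The percent of female-higher tags rose to 70.1 with TMM, 74.0 with RLE, 70.1 with upper quartile, 74.7 for merged loci (4311 male-higher) and 69.7 without mitochondrial tags, and reversed to 36.9 at a TPM of 10 or more (1090 female-higher, 1861 male-higher), a set with fewer tags. Under the scalings the list itself fixes the rise, since it holds no tag under 2-fold and male-higher tags can only drop out. Female-higher tags whose interval excluded 1 numbered 15547 with TMM, 15551 with RLE, 15547 with upper quartile, 4971 with a listed 0 taken as 1, and 3912 with 99% intervals. Male-higher ones numbered 1924 with RLE, 5827 with a listed 0 as 1 and 4936 with 99% intervals, so the female share of such tags, 58.5% as reported, reversed to 46.0% and 44.2% in the last 2 settings. The median fold of male-higher over that of female-higher tags counted in both sexes, 1.11 as reported, reversed to 0.96 with totals of the listed tags, 0.62 with TMM, 0.22 with RLE and 0.60 with upper quartile. The ratio of 10-base overlaps was 1.18 (0.98 to 1.42) with each start and end counted once. With at least 10 counts, 2631 tags were listed in females alone and 822 in males alone. With female counts thinned to the male total and at least 6 counts, 6894.5 were listed in females alone. The share of counts at 24 to 30 nt was 97.8% in females and 96.6% in males for distinct tags, and 96.8% and 95.7% without the 10 most abundant. The share at 24 or 25 nt was 9.17% of female-higher tags with 20 or more counts and 12.5% by counts; of male-higher tags it was 21.2% without mitochondrial tags and male-dominated regions and 26.1% by counts. The 10 listed tags with most male counts held 13.4% of the listed male counts without mitochondrial tags. Regions held 40.9% of female-higher and 67.5% of male-higher tags with gaps of 5 kb, 45.4% and 71.9% with 20 kb, and 34.6% and 60.7% with at least 10 tags (175 regions). The mitochondrial ratio was 7.19 with totals of the listed tags, 5.79 with TMM, 3.42 with RLE, 5.71 with upper quartile and 9.17 without its 10 most counted tags. Where the setting does not itself remove or rescale tags, the cause was not tested. No paired analysis was possible because the deposited table has 1 column per sex. For the same reason libraries were not left out in turn, and the DESeq2, limma and adjusted p alternatives were not run; absence of a low count filter changes nothing here, and sequence families, base composition, miRNA lists and Aalpi18529 were not analysed here. Depth limits single tags, since the interval found 20% of simulated 2-fold differences.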

Other observations

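All tests in this part were chosen only after the results were seen, and the loci were picked from those with most overlapping tags. Many tags were length and end variants stacked on the same bases. At NW_021837226.1 47867 to 47913, 31 overlapping tags were all female-higher, 10 of them started at base 47873, and their sum was 26.6-fold (22.7 to 31.3) higher in females. At NW_021839020.1 67138175 to 67138223, 46 tags within 49 bases were all male-higher, 4.65-fold (4.35 to 4.98) in sum. At NW_021837267.1 27236460 to 27236498, 31 tags were all male-higher, by 7.65-fold (6.99 to 8.38), and 10 of them ended at base 27236494. At NW_021838798.1 2995108 to 2995181, 30 tags were all male-higher, by 15.4-fold (11.5 to 21).

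On the mitochondrial sequence, 37 tags at bases 2708 to 2764 were 7.20-fold (6.60 to 7.87) higher in males and 36 tags at 2858 to 2891 were 11.7-fold (9.46 to 14.6) higher. Stacks of one direction were not the rule everywhere. At NW_021838153.1 167913308 to 167913415, 29 of 37 tags were male-higher and the others female-higher. Of the 2493 loci with 2 or more tags, 753 held tags of both directions.

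Tags listed in one sex alone numbered 12682 in females and 3868 in males. Counting noise of independent reads around one female share is argued against for tags of 10 to 20 counts. From 10 to 20 counts their number fell only from 654 to 47 in females and from 203 to 13 in males, and at 20 counts it was 39.3 times (lower limit 24.6) the most that a shared share allows, if tags do not become more numerous with count. At 6 counts, where 38.3% of the female and 36.2% of the male tags lie, the number was 1.38 times (lower limit 1.31) that given by noise, but this takes the tag IDs as a catalogue ordered by count, so noise and a difference cannot be told apart there. A difference between the sexes, or between single libraries, may underlie the rest and stayed untested without replicates. Reads without molecular identifiers are not independent molecules, so noise wider than that of independent reads stayed untested too.

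The listed mitochondrial tags were higher in males by 7.73-fold in sum, and tags under 2-fold are not in the list. For the listed tags, the ratio stayed above 1 under the other scalings, the lowest being 3.42 (lower limit 3.29). Since 466 of the 469 tags were listed as at least 2-fold higher in males, the list largely fixed that outcome. The scaling factors were also computed on a list without unchanged tags, so these values cannot decide on scaling as a cause. Of the mitochondrial tags 23.7% (19.9 to 27.8) were 27 or 28 nt, against 40.1% (39.0 to 41.3) of nuclear male-higher tags. In the male-dominated nuclear regions the share was 25.6% (22.6 to 28.9). Of these 757 tags, 268 came from NW_021837267.1 27236171 and 167 from NW_021838798.1 2994086. There 23.51% and 20.96% were 27 or 28 nt, at 34.6 and 26.6 tags per kb, against 38.3 on the mitochondrial sequence. Whether their tags also match the mitochondrial sequence was not tested, so that comparison may not be independent. A size profile apart from that of nuclear tags thus stayed open. More mitochondrial RNA in male bodies, more breakdown of it in the male libraries, and variation between libraries all stayed untested.

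Male-higher tags were more often 24 or 25 nt than female-higher ones, 15.9% of which were that short, though they were also more often 31 to 33 nt, at 3.99% against 1.85%. Without mitochondrial tags and male-dominated regions, 2.88% (2.47 to 3.33) of male-higher tags were 31 to 33 nt. Outside any region it was 2.00% (1.46 to 2.68) of male-higher and 1.36% (1.13 to 1.63) of female-higher tags, with overlapping intervals. Mitochondrial tags and male-dominated regions are argued against as the whole cause of the short tags, since 21.2% (20.1 to 22.2) of the other male-higher tags were that short. Low counts are argued against as the whole cause too. At 20 or more counts the share was 23.1% (21.4 to 24.8) of 2420 male-higher tags and 9.17% (8.0 to 10.5) of 2191 female-higher tags. That set kept mitochondrial tags and male-dominated regions, while the 21.2% included tags of low count. Both causes acting together were thus not tested. Outside any region the share at 24 or 25 nt was 24.2% of male-higher and 16.7% of female-higher tags. By counts of the leading sex it was 17.1% and 13.6%. All these intervals take overlapping tags as independent and are likely too narrow. A difference in piRNA makeup between the sexes may explain the larger share of short tags, as may a difference in size selection between libraries, and neither was tested.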
